A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

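The measurements were spot intensities on 2 DNA tag arrays, each with 2 channels. Per the labels, DNA was extracted from transformants of a pool of yeast deletion strains, the strain tags were amplified with labelled oligonucleotides, and Cy3 marked the linear and Cy5 the circular minichromosome on both arrays. Dyes were not swapped, so a dye bias of a tag cannot be separated from its ratio by design. The labels put both arrays in 1 group with n = 2.

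Per the file headers, the authors scanned the slides at 635 nm (Cy5) and 532 nm (Cy3) and quantified spots with GenePix Pro 5.0.0.49 without normalization. The deposited intensity values are each spot's median foreground and local background brightness. The deposited ratio per spot is the scanner software's median over pixels of the background-subtracted 635/532 ratio. The deposited log2 values are 1 number per open reading frame. Their scale and direction were found by comparison with the scanner values of the same array, where they ran as log2 of Cy5 over Cy3 (r = -0.97 with the opposite ratio on both arrays). Their medians were 0.0051 and 0.0109. How the authors normalized, filtered and combined tags is not given in the sources used here, and the centring is known only from these medians. Of 5908 rows, 4326 had a value on both arrays. The photomultiplier gain in the headers was 600 and 650 at 635 nm and 550 at 532 nm on both arrays.

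Each array had 27648 spots, of which 25858 held tags, 1406 spotting buffer and 384 nothing. The 12675 tag probes belonged to 5918 open reading frames. Background was corrected with limma's normexp (offset 50), and log2(linear/circular) was normalized within each array by loess (span 0.3, 4 iterations), fitted separately for uptags and downtags. Spots marked bad (22 on array 1 and 10 on array 2) or absent were left out. A tag probe was kept if at least 0.5 of its spots exceeded local background by 2 SD in at least 1 channel on each array, which left 10889 probes. Probes were averaged within a tag kind and then the tag kinds within a strain. Median signals over background at 635 and 532 nm were 1050 and 1576.5 on array 1 and 1425 and 1068 on array 2. Signal over background and the number of arrays limit the precision.

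Some choices were made after the data were seen. Spots that the scanner software did not find (1109 and 4354) were kept, the rule on the share of spots was set, probes marked R (881) were averaged with the others of their tag kind, and tags printed many times had weight 0 in the loess fit.

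Ratios were tested against 0 with limma (3.58.1, R 4.3.3) by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. Each strain had 1 residual degree of freedom, and the prior had 5.86 degrees of freedom and an SD of 0.181. Gene lists were tested with camera (inter-gene correlation 0.01), at the same threshold over 19 lists, with an estimated correlation, ranks and random lists matched on intensity beside it. The random lists were compared by the median ratio of their members, whereas camera works on means. Positions were tested with windows of 5 strains and 10000 shuffles, with strains ordered by systematic name (1000 shuffles for window medians). On data simulated on these arrays for the linear against circular comparison, with 5534 strains tested, all 48 strains changed by -1 and all 44 changed by 1 on the log2 scale were called, as were 15 of 22 changed by -0.5 and 11 of 22 changed by 0.5. All 25 strains changed by -2 and all 22 changed by 2 were called. Of the 5346 unchanged strains, 5 were called. The simulation gave all strains noise of the same size and equal changes on both arrays. The measured arrays differed in spread (SD of strain log2 ratios 0.286 and 0.450), so these rates need not hold for them.

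Gene symbols came from a reference table of assembly R64, which matched 5099 of the 5538 strains by systematic name. The other 439 kept the array's own name. No coordinates are given, since the files name no genome build. Genes of the fixed lists were matched by symbol. Of the lists given gene by gene, RAD50, RAD52, CTF8, BUB3, CIK1, MMS22, NUP133 and SLX8 were not above background on both arrays, and SUS1 had no spot on this array. Of the lists made by symbol, 14 of 132 cytosolic ribosome, 7 of 67 mitochondrial ribosome and 2 of 17 vacuolar ATPase genes were not measured here.

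The genes named in the report were chosen by a rule fixed before the data were examined. It took the 15 lowest and 10 highest called strains, every list member past the threshold over all strains or over its list, the 2 most distant members of each list, a few recombination genes and POL32 whatever their values, and the strains of the most extreme windows. Some genes that the rule takes are not reported here. Other members named beside them were chosen after their values were seen. An open reading frame of a neighbouring number is named beside EST1, without a check of overlap by coordinates.

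Alternatives fixed in advance covered background correction, the scanner software's ratios, the authors' values, normalization, filters, single tag kinds, the variance model, the gene list tests, window settings and leaving out each array. Added after the data were seen were strains with authors' values only, spots not found left out, probes marked R left out, and arrays scaled to equal spread. No sign-turned version was run. The arrays correlated at r = 0.72, which cannot show an exchange of dyes on both, so every direction rests on the dye assignment in the labels.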

Results

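The data came from a pooled screen in the budding yeast Saccharomyces cerevisiae. Each strain of the systematic deletion collection lacks 1 gene and carries short DNA barcodes, the uptag and the downtag, that flank the deleted gene. One portion of the pool received a circular minichromosome and another a truncated linear one, and the tags of the recovered transformants were amplified with a different dye for each transformation. The series title gives the subject as break-induced replication, a repair pathway in which a broken end invades a homologous sequence and is extended by DNA synthesis. Each of the 2 arrays, 1 per repeat of the experiment, held both transformations, with the linear one in Cy3 and the circular one in Cy5. The tag ratio therefore asks which deleted genes changed recovery of the linear molecule relative to the circular one.

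Tags of 5538 deletion strains were measured on both arrays, 4700 of them with both tag kinds and 838 with 1. On array 1, 98.0% of tag spots exceeded background in the Cy5 channel and 96.4% in the Cy3 channel. On array 2 these shares were 83.3% and 78.8%. Ratios are given as log2(linear/circular), mean ± SD of n = 2 arrays, so a negative value means fewer linear than circular transformants of that strain relative to the pool. Every direction rests on the labels' dye assignment, which no dye swap checks. The authors' deposited values run the other way, as circular over linear, and their mean correlated at r = -0.97 with the ratios used here across 4326 strains. Precision is limited by the number of arrays. The labels state that the experiment was repeated but do not say whether the pools were independent. The p-values therefore measure spread between these 2 arrays, which may be technical. The prior had 5.86 degrees of freedom against 1 per strain. A p-value thus rests mostly on spread pooled over strains, not on the strain's own SD.

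The linear/circular ratio was lower in 218 deletion strains and higher in 89, among 5538 tested with limma. The lowest ratios belonged to strains lacking YNR068C, at -2.08 ± 0.13 (4.23-fold lower), BUD3, a bud-site selection gene, at -2.06 ± 0.30, KRE1, a cell-wall glucan gene, at -2.04 ± 0.57, and ARD1, the catalytic subunit of an N-terminal acetyltransferase, at -2.00 ± 0.55. The highest belonged to strains lacking EFM3, a protein methyltransferase gene, at 2.11 ± 0.88 (4.33-fold higher), FUN30, a chromatin remodeller of long-range end resection, at 2.09 ± 0.40, and YEN1, a Holliday junction resolvase, at 1.92 ± 0.33. Telomerase mutants stood among the lowest as well, with EST3 at -1.65 ± 0.30 and EST2 at -1.62 ± 0.62.

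The other strains among the 15 lowest lacked the transcription factor genes MOT3 (-1.96 ± 0.18) and YAP3 (-1.87 ± 0.77), the phosphatase subunit gene PSY4 (-1.89 ± 0.70) and HNT3, which removes AMP from abortive DNA ligation products (-1.89 ± 0.0027, 1 tag kind). They also included END3, an endocytosis gene (-1.69 ± 0.098), NKP2, a kinetochore gene (-1.73 ± 0.78), NUP188, a nuclear pore gene measured with 1 tag kind (-1.64 ± 0.51), HUR1 (-1.68 ± 1.21) and YBL083C (-1.94 ± 1.38). The remaining strains among the 10 highest lacked FBP26, a fructose-2,6-bisphosphatase gene (1.89 ± 0.41), OYE2, an NADPH oxidoreductase gene (1.88 ± 0.58), YDR537C (1.86 ± 0.17), YPR197C (1.85 ± 0.097), MET22 (1.78 ± 0.026), YJL193W (1.71 ± 0.32) and YPR146C (1.56 ± 0.28). MET22 encodes a phosphatase of 3'-phosphoadenosine 5'-phosphate. Adjusted p-values of these 25 strains ran from 0.00178 for YNR068C to 0.0412 for HUR1 (limma, Benjamini-Hochberg). HUR1 and YBL083C lost their call in 6 of 18 tested settings each and NKP2 in 2. Without the filter on dim tags, HNT3 and NUP188 were at -0.86 each. The 307 calls made up 5.54% of strains, the smallest called change was 0.55 on the log2 scale, and 1253 strains had an unadjusted p below 0.05.

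A size rule without a test gave 37 strains at least 2-fold lower on both arrays and 14 at least 2-fold higher. Independent arrays with the same single-array shares would give 1.48 and 0.134. Array 2 was wider than array 1, with an SD of strain log2 ratios of 0.450 against 0.286. Array 1 alone held 38 strains at least 2-fold lower and 20 higher, and array 2 alone held 215 and 37. The counts of 218 lower and 89 higher strains moved to 17 and 8 with the scanner software's ratios, 127 and 54 with background subtracted, 395 and 184 with arrays scaled to equal spread, and 344 and 204 with tags as separate observations. Of 76 named called strains, 16, among them FUN30, EXO1, YEN1, PIF1, EST3, BUD3 and MOT3, kept their call under each of 18 tested alternative settings that gave them a value. No named called strain changed direction in these settings or on a single array. All called strains had the same sign on both arrays, so the single-array directions add no support.

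**Figure D1:**
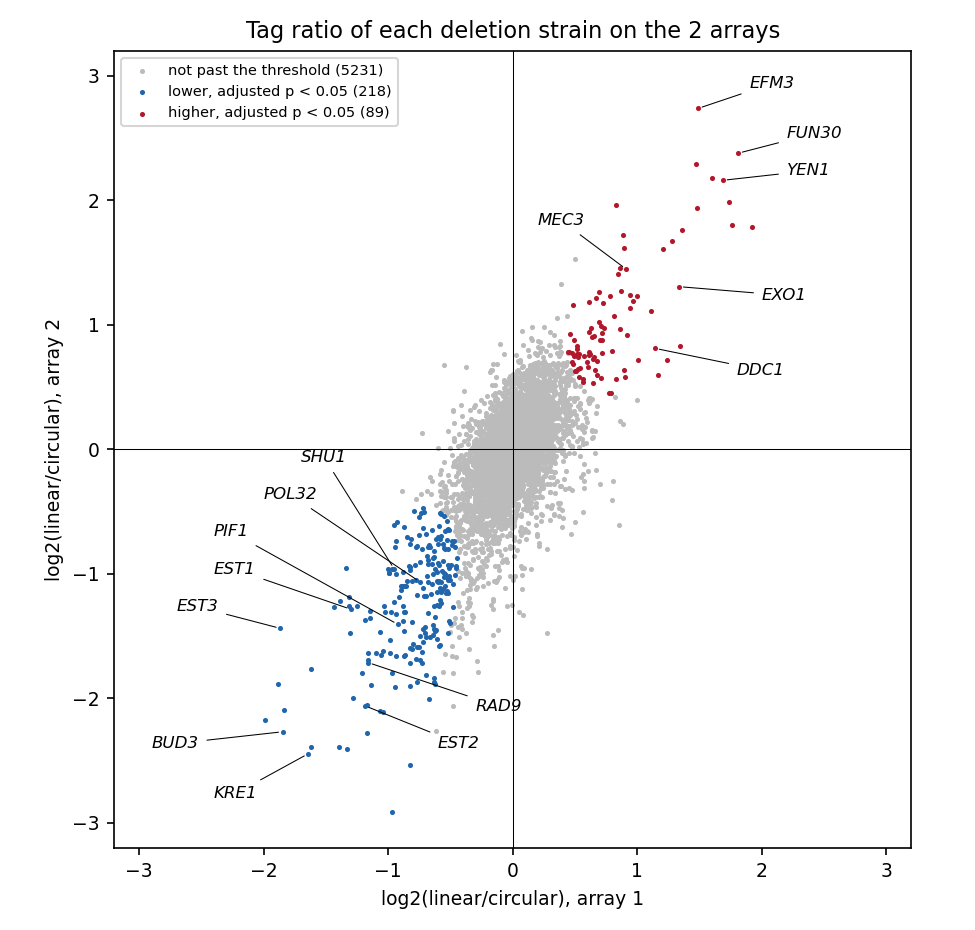
Log2(linear/circular) of each of 5538 deletion strains on array 1 (x axis) and array 2 (y axis), with strains past the adjusted threshold in blue (218 lower) or red (89 higher) and the rest in grey. The cloud is wider along array 2 (SD 0.450) than along array 1 (SD 0.286).

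The 2 arrays correlated at Pearson's r = 0.72 and Spearman's rho = 0.61 across 5538 strains, which are not independent replicates. Among 4700 strains with both tag kinds, uptags and downtags correlated at 0.71 on array 1 and 0.73 on array 2. The uptag repeated between arrays at 0.71 and the downtag at 0.67, and an uptag on one array against the downtag on the other gave 0.56 in both combinations. All 270 called strains with both tag kinds had the same sign for the uptag and the downtag. They were called on the mean of these 2 tags, so the shared sign is partly fixed by selection. In 13 of them the tags differed by at least 1 log2 unit, as in the strain lacking EST1, a telomerase subunit gene, with -2.36 for the uptag ACGGACACGACAGTAGTTCC and -0.22 for the downtag AGGACCGACATAATGCACGC. In the strain lacking EXO1, a resection exonuclease gene, the uptag TATGCGAGTCCAGCTCACTG gave 1.59 and the downtag CCATTGTCTGAAGCTGTGAG 1.05. FUN30 rested on its uptag TGCACAGCGACAATACGCGA alone. POL32, a DNA polymerase delta subunit gene, had -1.41 for the uptag and -0.39 for the downtag, and SRS2, a helicase gene, had -0.46 and -1.63. The linear channel exceeded background on 1 of 2 arrays for SRS2, PIF1, RAD55, GAL11 and RSM19, whose ratios are therefore less certain in size, and the circular channel on 1 of 2 for RAD6.

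Of the 19 gene lists fixed before the data were examined, 5 fell and 2 rose in limma's camera test with a preset correlation. None of the 7 passed with a correlation estimated from the arrays (smallest adjusted p = 0.631 in camera). With 2 arrays that version has 1 residual degree of freedom, so hardly any list could pass it. Its values, given with the lists, do not tell whether correlation between genes accounts for the calls. Among strains lacking strand exchange genes, 5 of 11 measured members were called lower, none higher, and 6 did not pass. The genes of the Shu complex, which acts in homologous recombination, were called lower, with PSY3 at -0.99 ± 9.3e-05 (1.99-fold lower), SHU1 at -0.96 ± 0.0052, SHU2 at -0.86 ± 0.11 and CSM2 at -0.64 ± 0.21. Of 18 tested settings, CSM2 lost its call in 5, SHU2 in 2, and SHU1 and PSY3 in 1 each. SRS2 lost its call in 2 of 16. SRS2, whose helicase acts against recombination, was at -1.05 ± 0.19, with the linear channel above background on 1 of 2 arrays, and ranged from -1.75 with background subtracted to -0.46 with uptags alone. RAD55 was at -0.65 ± 0.37, with an adjusted p of 0.0636 over all strains (limma). It passed when adjusted over the list alone, where 7 members were lower. RAD54 was at -0.13 ± 0.074 and RAD57 at 0.10 ± 0.24, and neither passed (adjusted p = 0.544 and 0.689, limma). RAD52 was not above background on both arrays and was not measured here. The list's mean was -0.50, with an adjusted p of 0.000339 in camera and an adjusted p = 0.631 with an estimated correlation.

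Among the end resection genes, 2 of 8 measured members were called higher and none lower, the same 2 as over the list alone. These were FUN30, at 2.09 ± 0.40 (4.27-fold higher), and EXO1, at 1.32 ± 0.023 (2.50-fold higher), which both act in long-range resection. MRE11 was at -0.12, XRS2 at 0.13, SAE2 at 0.32 and SGS1 at 0.29, none past the threshold, and RAD50 was not measured here. The list rose (mean 0.51, adjusted p = 0.0168 in camera), with an adjusted p = 0.631 with an estimated correlation. The call was lost under 5 of 18 alternative settings, among them random lists matched on intensity (adjusted p = 0.0689) and ranks (adjusted p = 0.0777).

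The DNA damage checkpoint genes divided. Of 9 measured, 5 were called higher, and they hold the 9-1-1 clamp and its loader subunit, with MEC3 at 1.18 ± 0.38 (2.26-fold higher), DDC1 at 0.98 ± 0.24, RAD17 at 0.88 ± 0.41 and RAD24 at 0.98 ± 0.40, and the kinase gene TEL1 at 0.67 ± 0.23. RAD17 and TEL1 lost their call in 3 of 18 tested settings each, DDC1, at 0.38 without the filter on dim tags, in 2, and MEC3 and RAD24 in 1 each. RAD9, the checkpoint adaptor gene, went the other way at -1.44 ± 0.39 (2.71-fold lower, adjusted p = 0.00693, limma), with its call lost in 1. DOT1, the histone methyltransferase gene, was at -0.53 ± 0.12 and passed over the list alone only (adjusted p = 0.0594 over all strains), which gives 2 lower and 5 higher there. DUN1 at -0.11 and CHK1 at -0.06 did not pass. The list as a whole did not pass in camera (mean 0.29, adjusted p = 0.0955). Random lists matched on intensity, which are compared by the median (0.67 for this list), gave an adjusted p of 0.0019. With an estimated correlation the adjusted p = 0.631.

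Strains lacking replication genes gave 2 calls among 16 measured members, both lower. PIF1, a DNA helicase gene, was at -1.16 ± 0.34 (1 tag kind, linear channel above background on 1 of 2 arrays), and POL32 was at -0.90 ± 0.23 (1.87-fold lower). POL32 lost its call in 3 of 18 tested settings. PIF1 ranged from -1.73 with the scanner software's ratios to -0.94 without background correction. DPB4 at -1.03 ± 0.78 and DPB3 at -0.55 ± 0.27, which encode DNA polymerase epsilon subunits, passed over the list alone, where 4 members were lower. REV1, REV3 and REV7, the translesion synthesis genes, were at 0.16, -0.08 and -0.17, and none passed. CTF8 was not measured here. The list fell (mean -0.30, adjusted p = 0.0168 in camera), with an adjusted p = 0.631 with an estimated correlation. The call was lost under 6 of 18 alternative settings, among them the authors' values (adjusted p = 0.111).

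**Figure D2:**
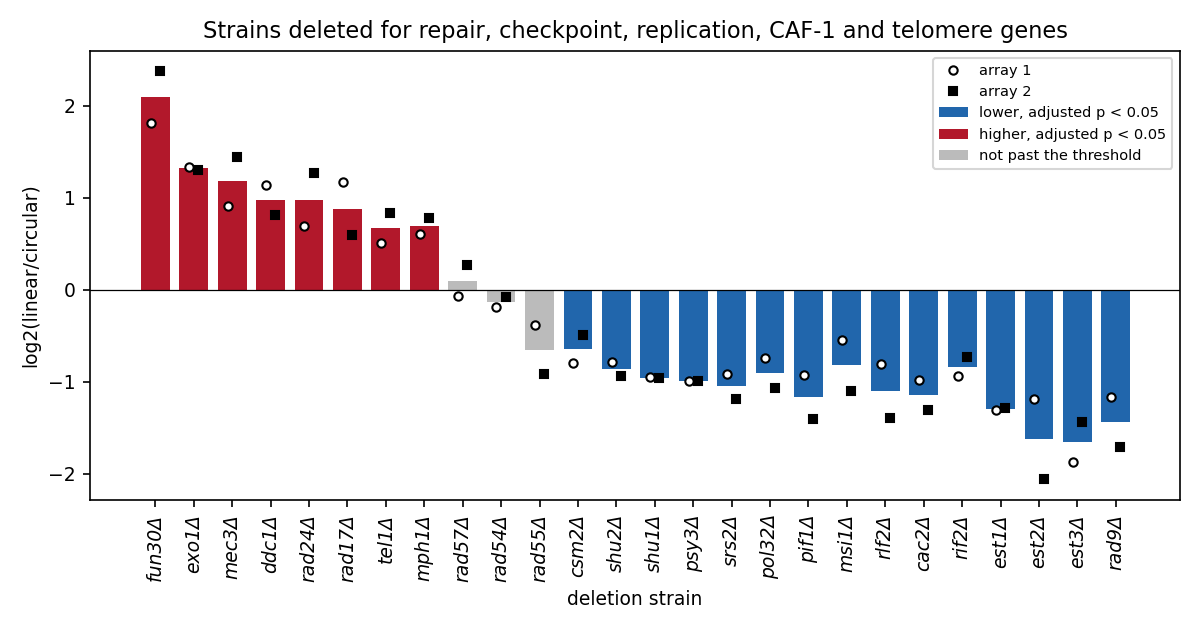
Log2(linear/circular) of strains lacking repair, checkpoint, replication, CAF-1 or telomere genes (x axis), with bars for the mean of 2 arrays, open circles for array 1 and filled squares for array 2, coloured by limma's call. RAD9 (-1.44) lies below 0 while MEC3, DDC1, RAD24 and RAD17 (0.88 to 1.18) lie above it on both arrays.

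Telomere maintenance genes gave 4 lower calls and 1 higher among 9 measured members, also when adjusted over the list alone. All 3 telomerase protein genes were lower, with EST3 at -1.65 ± 0.30 (3.14-fold), EST2 at -1.62 ± 0.62 (3.08-fold) and EST1 at -1.29 ± 0.012. EST1 ranged from -2.36 with uptags alone to -0.22 with downtags alone, and lost its call in 2 of 18 tested settings, as did EST2. RIF2, a telomere length regulator gene, was at -0.84 ± 0.14, with its call lost in 1 setting, whereas RIF1 at -0.11 did not pass. TEL1, shared with the checkpoint list, was the member called higher. The strain of YLR232W, the open reading frame numbered next to EST1, was lower as well, at -0.78. The list fell (mean -0.59, median -0.26, adjusted p = 0.00725 in camera), with an adjusted p = 0.631 with an estimated correlation. It did not pass against random lists matched on intensity (adjusted p = 0.0689) or with downtags alone (adjusted p = 0.101).

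All 8 strains lacking the histone variant H2A.Z or its SWR1 loading complex had mean ratios below 0, and 2 were called lower over all strains. SWC3, measured with 1 tag kind, was at -0.95 ± 0.61 and YAF9 at -0.86 ± 0.40. SWC3 lost its call in 7 of 15 tested settings and YAF9 in 1 of 18. Adjusted over the list alone, 6 were lower, which adds ARP6 (-0.71 ± 0.38), VPS72 (-0.56 ± 0.19), VPS71 (-0.50 ± 0.43) and HTZ1, the H2A.Z gene (-0.46 ± 0.35). VPS72 had -1.01 for the uptag and -0.11 for the downtag. The list fell (mean -0.64, adjusted p = 0.000339 in camera), with an adjusted p = 0.696 with an estimated correlation. Its mean was -0.28 on array 1 and -0.99 on array 2.

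Among histone chaperone genes, all 3 subunits of CAF-1, which deposits histones behind the replication fork, were called lower, with CAC2 at -1.14 ± 0.23 (2.20-fold), RLF2 at -1.10 ± 0.41 and MSI1 at -0.82 ± 0.39. MSI1, with -0.51 for the uptag and -1.13 for the downtag, lost its call in 4 of 18 tested settings, and CAC2 and RLF2 each in 1. RTT101, a cullin gene, was higher at 0.56 ± 0.090 and lost its call in 5. ASF1 at 0.12, RTT109 at -0.08, HIR1 at 0.12, HIR2 at 0.06, HIR3 at 0.09 and HPC2 at 0.41 did not pass, and MMS22 was not measured here. The counts were 3 lower and 1 higher of 11 measured, the same when adjusted over the list alone. The list did not pass (adjusted p = 0.669 in camera), and its median of 0.06 and its mean of -0.17 differ in sign.

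Mitochondrial ribosome genes gave 7 lower calls and 1 higher among 60 measured members. The lowest called were MRPL17 at -1.26 ± 0.56, MRPL13 at -1.18 ± 0.58, MRP2 at -1.10 ± 0.57 and MRPL7 at -0.90 ± 0.45, followed by MRPL6 (-0.76 ± 0.23), MRPS28 (-0.66 ± 0.30) and MRPL4 (-0.59 ± 0.085). MRPL44 was higher at 0.85 ± 0.20. MRPS28 lost its call in 8 of 18 tested settings, MRPL7 in 5, MRPL4 in 3, MRPL17, MRP2 and MRPL6 in 2 each, and MRPL13 and MRPL44 in 1 each. Adjusted over the list alone, 10 were lower and 2 higher, which adds RSM19 (-1.14 ± 0.93), MRPL9 (-0.84 ± 0.58), MRPS12 (-0.55 ± 0.35) and RSM18 (0.58 ± 0.28). The list fell (mean -0.19, adjusted p = 0.0405 in camera), with an adjusted p = 0.716 with an estimated correlation. The call was lost under 7 of 18 alternative settings, and the list's mean was -0.07 on array 1 and -0.32 on array 2.

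Cytosolic ribosome genes had a list mean of 0.08 over 118 measured members, 6 called higher and 3 lower. The list rose in camera (adjusted p = 0.0168), with an adjusted p = 0.631 with an estimated correlation. RPS23A was at 0.94 ± 0.38, RPL2A at 0.75 ± 0.042, RPL26B at 0.69 ± 0.33, RPL16A at 0.65 ± 0.078, RPL6A at 0.65 ± 0.017 and RPL26A at 0.64 ± 0.18. RPL15B at -1.25 ± 0.15 (2.38-fold), RPL34B at -0.94 ± 0.34 and RPS25A at -0.67 ± 0.18 were lower. The call was lost for RPL26B in 6 of 18 tested settings, for RPL26A in 4, RPL16A and RPS25A in 3 each, RPS23A and RPL6A in 2 each, and RPL2A and RPL34B in 1 each. Adjusted over the list alone, 11 were higher and 5 lower, among them RPL37B (0.62), RPL35B (0.60), RPS7B (0.57), RPS6B (0.56) and RPS17B (0.52) above 0 and RPL20A (-0.52) below it. The list's call was also lost with downtags alone (adjusted p = 0.067).

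Among the structure-selective nucleases, YEN1 was the 1 member of 8 called, at 1.92 ± 0.33 (3.80-fold higher). MUS81 at -0.19 and MMS4 at -0.32, which form another resolving nuclease, and RAD1 at 0.37 did not pass, nor did the list (adjusted p = 0.0979 in camera), which passed against random lists matched on intensity (adjusted p = 0.0365) and not with an estimated correlation (adjusted p = 0.631). Of 12 measured SAGA coactivator genes, SGF29 (0.92 ± 0.0026) and SGF11 (0.79 ± 0.13) were called higher, and UBP8 (0.52 ± 0.048), which encodes a deubiquitinase of the complex, passed over the list alone, where 3 were higher. The SAGA list did not pass (mean 0.21, adjusted p = 0.0576 in camera) but passed under 7 of 18 alternative settings, with adjusted p-values over the 18 from 0.023 with both tags required to 0.631 with an estimated correlation. SUS1 was not measured here. In Mediator, the kinase gene SSN3 (1.08 ± 0.16), SSN2 (0.58 ± 0.14) and NUT1 (1.13 ± 0.40) were higher and SRB2 (-1.43 ± 0.69) was lower among 14 measured members. SRB2 had -1.98 for the uptag and -0.87 for the downtag. SSN2 lost its call in 6 of 18 tested settings, SRB2 and SGF11 in 2 each, and SSN3, NUT1 and SGF29 in 1 each. GAL11 (-0.54 ± 0.15) and MED1 (0.43 ± 0.047) passed over the list alone, giving 2 lower and 4 higher. The Mediator list did not pass (adjusted p = 0.661 in camera), with a mean of 0.05 and a median of -0.05.

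Of 7 mismatch repair genes, MSH6 was called lower at -0.64 ± 0.088. Adjusted over the list alone, 3 were lower, and the list did not pass (adjusted p = 0.0979 in camera). Among 6 post-replication repair genes, MPH1, a helicase gene, was higher at 0.70 ± 0.12 and RAD18, a ubiquitin ligase gene, was lower at -0.77 ± 0.36. RAD6 (0.45 ± 0.34, 1 tag kind) passed over the list alone, with 1 lower and 2 higher there, and the list did not pass (adjusted p = 0.467 in camera). Of 18 measured kinetochore and spindle checkpoint genes, NKP2 was lower at -1.73 ± 0.78 and MCM16 higher at 0.74 ± 0.23. Of 18 tested settings, RAD18 lost its call in 5, MSH6 in 3, and MPH1 and NKP2 in 2 each, and MCM16 lost it in 3 of 15. Over the list alone, 3 were lower, adding CHL1 (-0.70 ± 0.53) and BIM1 (-0.60 ± 0.50), and 5 were higher, adding CHL4 (0.52 ± 0.078), MCM22 (0.46 ± 0.077), CTF3 (0.46 ± 0.11) and MAD2 (0.38 ± 0.040). MCM22 had 0.90 for the uptag and 0.03 for the downtag. BIM1, measured with 1 tag kind, ranged from -0.77 to -0.02 over 15 tested settings. The kinetochore list did not pass (adjusted p = 0.862 in camera), and its mean of -0.06 and median of -0.10 lay below 0 while the test pointed up. BUB3 and CIK1 were not measured here.

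No member passed in 4 lists, over all strains or over the list alone. Among 6 end-joining genes the most distant from 0 were YKU70 at -0.26 and POL4 at 0.12 (list adjusted p = 0.862 in camera). Among 7 nucleotide excision repair genes they were RAD7 at -0.34 and RAD23 at -0.24 (adjusted p = 0.435). Among 15 measured vacuolar ATPase genes they were VMA4 at 0.44 and VMA21 at 0.34 (adjusted p = 0.357). Among 7 measured nuclear pore and SUMO genes they were NUP60 at -0.51 and NFI1 at 0.39 (adjusted p = 0.357), and NUP133 and SLX8 were not measured here.

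**Figure D3:**
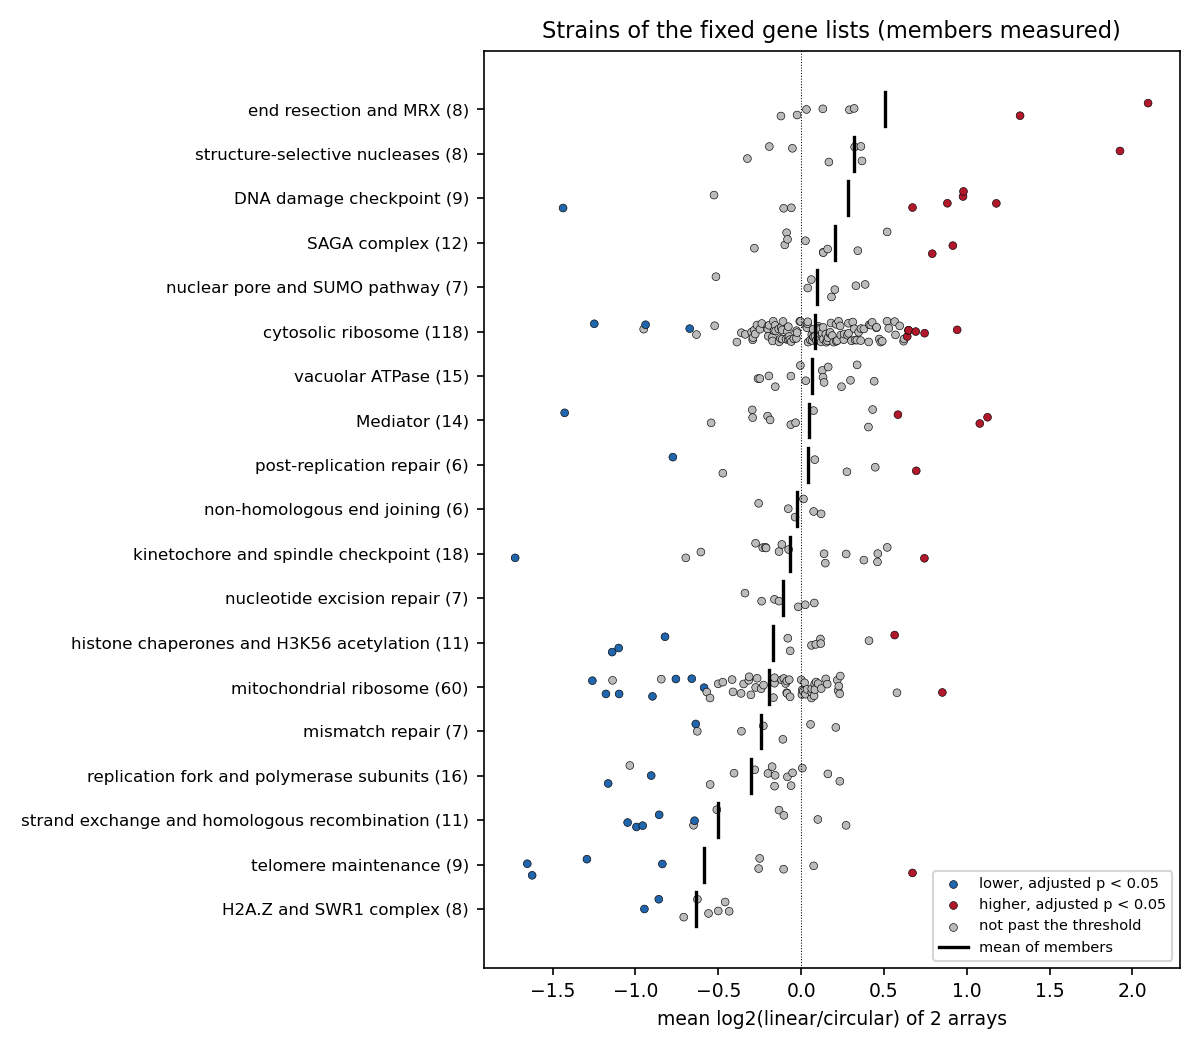
Mean log2(linear/circular) of 2 arrays (x axis) for each measured member of the 19 fixed gene lists (y axis, ordered by list mean, member number in brackets), with black bars for list means and colours for limma's calls. All 8 members of the H2A.Z and SWR1 list lie below 0, while the checkpoint list holds members from -1.44 to 1.18.

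Windows of 5 neighbouring strains were compared along the chromosomes, because the linear minichromosome can share sequence with a chromosomal region that the labels do not name. The lowest window ran from YML107C to YML102W and had a mean of -0.91. It held PML39 (-0.16 ± 0.13), MDM1 (-0.55 ± 0.012), NUP188 (-1.64 ± 0.51), YML102C-A (-1.09 ± 0.59) and CAC2 (-1.14 ± 0.23). MDM1 lost its call in 6 of 18 tested settings and YML102C-A in 3. The highest window ran from YJR126C to YJR130C and had a mean of 0.55, with EFM3 at 2.11 ± 0.88 beside VPS70 (0.08), RSF2 (0.18), YJR128W (0.23) and STR2 (0.15). Neither passed among 5474 windows (1-sided permutation tests at each end with 10000 shuffles of the strains, family-wise p = 0.0783 for the lowest and 0.807 for the highest). The highest window by its median passed (0.78, permutation p = 0.02) and was another one, from YOR364W (1.11) to RAD17 (0.88). This was 1 of 20 alternative settings, which include the single arrays, where no test was run.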

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

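Of the tests in this part, the tag covariance test and the weaker-tag test were chosen after the results they measure were seen.

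Spotting buffer spots, which hold no tag, exceeded background where empty positions did not. On array 1, 25.2% of 1406 buffer spots did so in the Cy5 channel and 26.0% in the Cy3 channel, and on array 2 the shares were 15.2% and 14.4%, against 0% of 384 empty positions. Their median signal over background was 5 in the Cy5 channel of both arrays, and 15 and 8 in the Cy3 channel.

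Strain ratios repeated between the 2 arrays (r = 0.72). With Cy3 as the linear dye on both arrays, a dye bias of single tag sequences could repeat as well. The uptag and downtag of a strain differ in sequence, yet their covariance between arrays was 0.806 of that of the same tag (95% bootstrap interval 0.785 to 0.828), which argues against single-tag dye bias as the main source. The remainder leaves room for such a bias in part of the signal. A difference in recovery of the linear molecule between strains remains open as the design's own explanation, as do effects common to both tags of a strain.

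Of the 89 called higher strains, 66 lie outside the fixed lists, EFM3, FBP26 and OYE2 among them, and 59 of these have both tag kinds. Hybridisation of 1 tag to another strain's product as the whole cause would leave the weaker tag near 0, whereas its median was 0.69 (95% bootstrap interval 0.63 to 0.80). Both tags reached 0.5 in 49 of 59 strains (83.1%, exact interval 71.0% to 91.6%), which spans the 80% set beforehand, so for single strains this explanation stays open. Carry-over between printed spots would raise the tags printed beside them, and the median of 197 such tags was -0.027. Neighbouring tags that belong to the same 59 strains were left out, and a median does not show a rise in a few tags. Carry-over into some neighbours therefore stays open. A biological difference in recovery of the linear molecule remains open and untested.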

How the results depend on the processing

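Settings added after the data were seen are the restriction to strains with authors' values, the removal of probes marked R or of spots not found, and the scaling of arrays to equal spread. The 76 named called strains kept their direction in 1498 of 1498 alternative values, and 16 kept their call under each of 18 tested settings that gave them a value; calls were lost for 58 with the scanner software's ratios, 22 with background subtracted, 20 with uptags alone, 15 with downtags alone, 15 without the filter on dim tags, 10 with only strains that have authors' values, 5 without probes marked R, 3 with robust eBayes, 2 with tags as separate observations, and 1 each with the authors' values and with both tags required. The alternative values reuse the same 2 arrays, on which all called strains had the same sign, so the kept directions are not independent support. The lists not called include 10 values that reversed, as given here. Array agreement ranged from r = 0.671 to 0.732. Where a value changed, the cause was not tested, except that fewer tags or strains entered single-tag and restricted settings. Tag spots above background (83.3% and 78.8% on array 2) limit dim tags. Each array held both transformations, so the tested ratio is itself the paired comparison, and with 1 group no further pairing was possible. Counts by test and the list tests have no value with 1 array, where list means stand without a test. These means differed in sign between arrays for post-replication repair, Mediator, kinetochore, end joining and nuclear pore genes, none of them called.

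Against 218 lower and 89 higher calls, higher calls were 140 without background correction, 158 with the authors' values, 135 with loess over both tag kinds and 58 with downtags alone, and lower calls were 332 with median centring. Background subtraction gave 127 lower and 54 higher, the scanner software's ratios 17 and 8, equal spread 395 and 184, and tags as separate observations 344 and 204. Strains at least 2-fold lower on both arrays (37) became 24 without background correction, 56 with the scanner software's ratios and 61 with equal spread. With single arrays they ranged from 38 to 215, and higher ones from 20 to 37.

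Against 5 lists called lower and 2 higher, lower lists numbered 3 with the authors' values, with strains having authors' values and with downtags alone, 2 against random lists and 0 with an estimated correlation. Higher lists numbered 1 without the filter on dim tags and with ranks, and 0 with downtags alone and an estimated correlation. The highest window passed by its median only (0.78).

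Reversed values were post-replication repair without background correction (-0.019), with the authors' values (-0.13), with the circular channel above background (-0.038), with both tags required (-0.038), with downtags (-0.073) and with strains having authors' values (-0.12). Others were Mediator with background subtracted (-0.028), kinetochore genes with the authors' values (0.028) and uptags (0.017), end joining with uptags (0.030), RAD54 (YGL163C) with uptags (0.0089) and STR2 (YJR130C) with downtags (-0.042).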

Other observations

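The gene groups given here lie outside the fixed lists and were assembled after the values were seen, because of them, so their counts are descriptions without a test. Over all strains 5.54% were called. All 18 measured genes of the ESCRT complexes and Vps4, which sort membrane proteins into multivesicular bodies, had mean ratios below 0, with 8 called lower and a median of -0.68. VTA1 was at -1.39 ± 0.12 (2.62-fold lower, n = 2 arrays), DID2 at -1.28 ± 0.13, SNF7 at -1.25 ± 0.79 and VPS4 at -1.21 ± 0.56. Elongator, a tRNA-modifying complex, had all 5 measured members below 0 and 3 called lower, with ELP4 at -1.34 ± 0.94, IKI3 at -1.27 ± 0.63 and ELP6 at -1.22 ± 0.67. In the Rpd3L histone deacetylase, 10 of 12 members lay below 0 and 4 were called lower, led by SAP30 at -1.37 ± 0.38 and PHO23 at -1.21 ± 0.54, while RPD3 itself was at -0.14.

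Of 3 nonsense-mediated mRNA decay genes, NMD2 at 1.09 ± 0.36 and UPF3 at 0.98 ± 0.37 were called higher, and NAM7 at 0.70 ± 0.43 was not past the threshold (adjusted p = 0.0633, limma). DOM34 (1.16 ± 0.42) and HBS1 (0.91 ± 0.070), partners in the rescue of stalled ribosomes, were both called higher. Of 12 genes of dynein, dynactin and spindle position, 9 lay below 0, with a median of -0.19. The 5 called lower were KAR9 at -1.38 ± 0.58, ARP1 at -1.33 ± 0.41, BFA1 at -1.30 ± 0.12, BUB2 at -1.22 ± 0.11 and JNM1 at -0.65 ± 0.097. The others were not called and lay between -0.20 (NIP100) and 0.10 (NUM1), with DYN1, the dynein heavy chain gene, at 0.08.

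The 439 measured open reading frames that are not in the reference table held 35 calls. A hypothesis, tested after some of these pairs were seen, is that deleting such a frame may also remove part of a neighbouring gene. Ratios of 764 pairs of neighbouring numbers with 1 such frame correlated at 0.302, against 0.105 for 4275 pairs of listed genes, a difference of 0.197 (1-sided permutation p = 0.0002, 10000 permutations). Neighbouring pairs share strains but were shuffled as if independent, so this p-value may be too small. Both strains were called in 12 such pairs and had the same sign in 12. Among pairs of listed genes with both called, 8 of 15 had the same sign, a contrast that was not tested. The 12 pairs hold 10 of the 35 called unlisted frames, and the other called frames were in no such pair. Examples are YLR232W (-0.78) and EST1 (-1.29), YKR035C (-0.93) and DID2 (-1.28), YNL120C (-1.15) and NCS2 (-1.40), and YPR123C (0.95) and CTR1 (0.85). The result is consistent with the hypothesis, but overlap was not checked by coordinates, and pairs of neighbouring frames can differ from pairs of listed genes in other ways, such as their spacing.

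Tags of 367 open reading frames exceeded background on array 1 only, and of 0 on array 2 only.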
